A study of Homo sapiens with 12 samples.

How the data were processed

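RNA was measured in single cells sorted from blood and from melanoma metastases of the same 5 donors, in 12 libraries made with the 10x Genomics 3' V2 assay. Each donor gave 1 blood library. Donors 1 to 4 gave 1 tumor library each, and donor 5 gave 3, labelled center, cortex and nodule. Per the labels, the gate took viable single cells of lymphocyte size that carried CD45 and CD56 and lacked CD3, CD4, CD8a, CD14, CD15 and CD163, and the sorted cells are called natural killer (NK) cells. Tumor tissue was dissociated with an enzyme kit, and red cells in blood were lysed with a buffer, so dissociation and tissue coincide in every donor.

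The deposited matrices hold counts, that is, unique molecular identifiers (UMIs) per gene and barcode, with no normalization. The authors had called barcodes as cells before deposit. Per the labels, reads were aligned to hg38 with Cell Ranger 3.0.2; the matrix headers name version 3.0.0 for donor 3 and 3.0.2 for donors 4 and 5, and the other headers name none. The gene tables hold 33694 genes for donors 1 to 3 and 33538 for donors 4 and 5, which was treated as a batch. The 32991 gene identifiers found in every library were used, and they held 99.6% to 99.8% of each library's UMIs. From these, 130 Y-linked, XIST and TSIX genes were left out, which left 32861. Summed counts were compared between all 66 pairs of libraries, and 0 pairs were identical.

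Cells were kept with at least 300 genes and at most 10% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.05. Of 40823 barcodes, 40153 passed the filters, 337 (0.839%) were called doublets, 271 of them in blood library 5, and 39816 were kept. Counts were scaled to 10000 per cell and log-transformed. Of 2000 variable genes, 1853 were used after mitochondrial, ribosomal protein, hemoglobin, KIR and HLA genes and segments of antigen receptor genes had been left out. With 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1, the cells fell into 23 clusters, with no correction between donors. Clusters were named from marker lists by a score, and a name needed at least 3 markers detected at 50 CPM or more. A cluster was left unnamed where its 10 leading genes held as many or more markers of another cell type. The details of this last rule, including the check for hemoglobin and platelet genes, were settled after the clusters had been seen. NK-like clusters were divided by score into a CD16-high class and a CD56-bright class.

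Raw counts of the kept cells were summed per donor and tissue, with the 3 regions of donor 5 in 1 tumor sum, which gave 5 blood and 5 tumor sums. Sums of at least 20 cells were used, and no sum fell below this. Tumor was compared with blood in all NK-like cells and in each class by the quasi-likelihood F-test of edgeR 4.0.16 with TMM scaling, the filterByExpr filter and donor as a block (R 4.3.3). The test of whether the tumor effect differed between the classes used the tissue by class interaction, with donor by class as blocks. It held no donor by tissue term, although both classes of a donor and tissue came from the same libraries. A donor's own tumor effect shared by both classes therefore stayed in the residual. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 or less. CPM is a gene's share of the UMIs of a sum, where 1% equals 10000 CPM. Errors are the SD over 5 donors for CPM, and for log2 fold changes the standard error (SE) derived from the F statistic, which is not given where the p-value was above 0.9.

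As a check of the pairing, each sum's deviation from its tissue mean was correlated across genes between blood and tumor. The correlations within a donor were 0.452, 0.550, 0.361, 0.704 and 0.862 for donors 1 to 5. The highest with another donor's tumor were 0.256, 0.244, 0.193, -0.0793 and -0.133. Genes are not independent replicates, so no p was computed.

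The 28 gene lists, the comparisons, the cell type markers and the rule for named genes were fixed before the data were examined. Of the 442 genes in the lists, 45 stood in more than 1 list and 44 were also markers that named NK-like cells or their classes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists, and again with an estimated correlation and with fry. The rule named, for all NK-like cells, the 14 largest rises and the 14 largest falls in log2 fold change among called genes with a mean of at least 50 CPM and the same direction in all 5 donors. It also named up to 4 members per list with the smallest adjusted p, at most 3 per direction, and 2 members with the highest mean where a list had no call. For each class and for the interaction it named up to 6 genes in each direction. KIR and HLA genes, gene segments of antigen receptors and mitochondrial genes were not named. Some members of the lists are not reported here, and those were dropped from the named genes without replacement. Other list members are named where a count was 5 or fewer or where they fill out a group, and those were chosen after their values were seen.

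Region values of donor 5 are pooled CPM with exact Poisson intervals at 95%. Members of 5 lists (chemokine ligands, cytotoxic granule genes, tissue residency, the CD16-high program and the CD56-bright program) with at least 100 counts were compared, and the 6 with the largest ratio between regions are named. Shares of cells carry Wilson intervals at 95%. All such intervals cover counting error only.

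Results were fitted again with no replicate block, DESeq2 1.42.0, RLE size factors, no low-count filter, each donor left out, all cells passing the filters, no cell filter, at least 500 genes, at most 5% mitochondrial UMIs, doublets kept, Leiden resolution 0.5 (16 clusters), sums thinned to the smallest, each tumor region alone, each annotation batch alone and calls of at least 2-fold. For regions, cells were also thinned to 2000 UMIs each, a number set after the depths had been seen. Added after the data had been seen were a cluster led by HBA2, KLRC2 and CD3G counted as NK-like, donors 1 and 5 left out together, and an equal mix of both classes in blood and tumor. For that mix, each donor's cells of each class were drawn down to the tissue with fewer. Blood and tumor thus matched, but the classes stayed unequal in number. Other splits of the same sums were fitted 100 times per comparison, and 16 times for the interaction, which has no more.

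The fits were tested on simulated data with 200 changed genes. At 2-fold they recovered 81.8% of changed genes for all NK-like cells, 67.7% for CD16-high cells, 81.0% for CD56-bright cells and 47.8% for the interaction. At 1.5-fold they recovered 36.9%, 37.5%, 39.4% and 6.06%, and 6 or 7 calls per comparison were false. The simulated sums for the interaction held no donor's own tumor effect shared by both classes. In the same test, camera at the preset correlation called the 1 shifted list and also 4 of the 27 others, of which 1 shared no gene with it. Near-identical genes (CCL3 and CCL3L1, CCL4 and CCL4L2, XCL1 and XCL2, HSPA1A and HSPA1B, HBA1 and HBA2) share reads that align equally well to both, so how their counts divide is uncertain. Analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.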

Results

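Gene expression was measured as UMI counts in single cells sorted as NK cells from the blood and the melanoma metastases of 5 donors. NK cells are lymphocytes that kill infected or transformed cells and secrete cytokines. The 12 libraries comprised 5 from blood and 7 from tumor, of which 3 came from separate regions of the tumor of donor 5. The labels give matched samples from each patient, so donors were compared with themselves.

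Blood libraries 1 to 5 held 6969595, 11024905, 10712806, 18935455 and 42099800 UMIs. Tumor libraries of donors 1 to 4 held 8701616, 5702457, 11238647 and 20809740 UMIs. The center, cortex and nodule libraries of donor 5 held 6904399, 5167830 and 8913930 UMIs. Kept cells held a median of 2133 to 4296 UMIs in blood libraries and 2353 to 6178 in tumor libraries. Donors 1 to 3, with the larger gene annotation, had the lower median depth in each tissue.

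The first question was which cells the gate had yielded. NK-like cells, named by transcripts such as KLRF1, NKG7 and GNLY, made up 18722 of the kept blood cells (74.2%) and 12029 of the kept tumor cells (82.4%). Innate lymphoid cell (ILC)-like cells, with KIT among their leading genes, numbered 843 (5.77%) in tumor and 7 (0.0278%) in blood. No cluster received the ILC-like name at the lower Leiden resolution. T-like cells made up 2837 blood cells (11.2%) and 666 tumor cells (4.56%), although the gate excluded CD3, CD4 and CD8a. Myeloid-like cells made up 2043 (8.10%) and 469 (3.21%). Of these, 1533 blood cells and 18 tumor cells lay in a cluster with CD14 among its leading genes, although the gate excluded CD14. Another 324 of the tumor cells lay in a cluster led by FCER1A, PLD4 and LILRA4, and 126 in one with CLEC9A among its leading genes. Melanoma-like cells numbered 192 (1.32%) in tumor. B-like cells numbered 266 in blood and 48 in tumor.

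**Figure D1:**
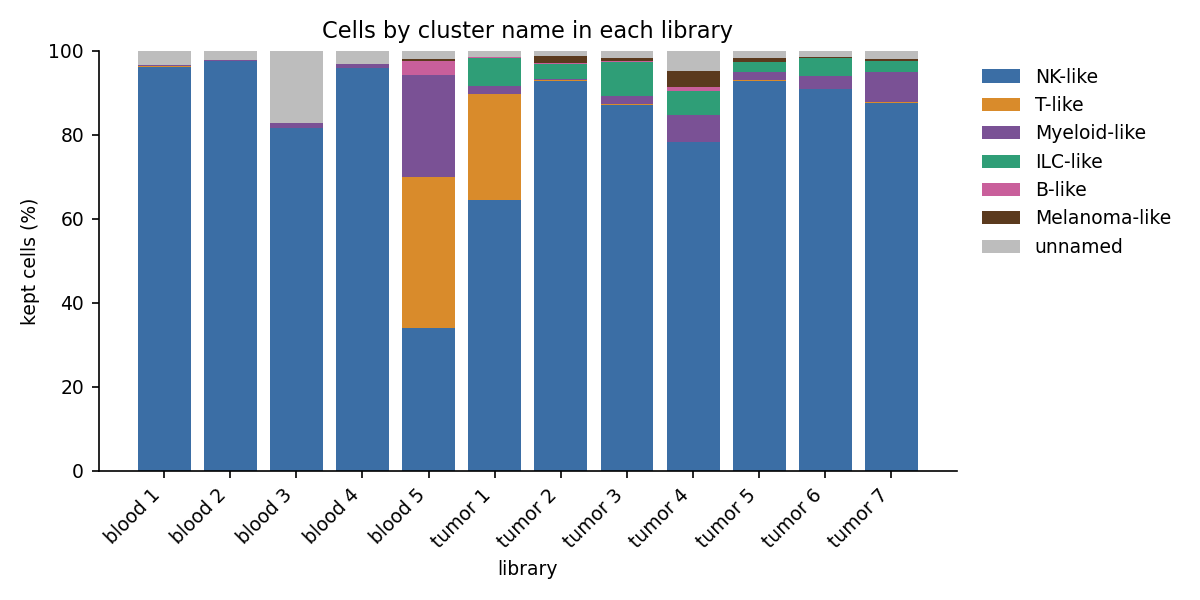
Percent of kept cells by cluster name in each of the 12 libraries (bars stacked to 100%). NK-like cells ranged from 34.1% in blood library 5 to 97.6% in blood library 2.

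These totals rested on few libraries. Blood library 5 was 34.1% NK-like (Wilson 95% interval 33.1% to 35.2%), 35.8% T-like and 24.3% myeloid-like, and it held 2831 of the 2837 T-like blood cells. The other blood libraries were 81.6% to 97.6% NK-like. Tumor library 1 was 64.4% NK-like and 25.3% T-like, with 643 of the 666 T-like tumor cells. A further 1308 blood cells and 351 tumor cells were left unnamed. Among them were clusters led by HBA2, KLRC2 and CD3G (936 blood and 23 tumor cells), by immunoglobulin segments with TYMS, MKI67 and TOP2A (290 and 328 cells), and by the platelet gene PPBP (82 blood cells). Shares were not tested between tissues, because sort yield and dissociation differed with tissue.

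The main comparison asked how NK-like cells in tumor differed from those in the blood of the same donor. Immediate-early transcription factors were far higher in tumor: EGR1 averaged 0.165 ± 0.0735 CPM in blood and 134 ± 79.5 CPM in tumor (SD, n = 5), a log2 fold change of 9.43 ± 0.25 (SE). RGS1, a regulator of G protein signaling that is high in tissue lymphocytes, rose by 6.70 ± 0.28 from 6.06 ± 2.12 to 672 ± 404 CPM. CD69, an activation and tissue-retention receptor, rose by 4.11 ± 0.29 from 170 ± 64.6 to 2969 ± 1457 CPM. Genes of circulating cytotoxic NK cells were lower: FGFBP2, a secreted protein of cytotoxic lymphocytes, fell by 2.94 ± 0.44 from 1641 ± 587 to 209 ± 106 CPM, and CX3CR1, the fractalkine receptor, fell by 2.90 ± 0.41. FCGR3A, which encodes the antibody receptor CD16, fell by 1.62 ± 0.31 from 1199 ± 316 to 435 ± 292 CPM.

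All 6 of those genes moved the same way in 5 of 5 donors. Their adjusted p, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was 9.47e-07 for EGR1, 6.5e-06 for RGS1, 7.91e-05 for CD69, 0.00259 for FGFBP2, 0.00202 for CX3CR1 and 0.0067 for FCGR3A. On hg38, EGR1 (ENSG00000120738) lies on chromosome 5 from 138465490 to 138469315 and RGS1 (ENSG00000090104) on chromosome 1 from 192575727 to 192580031. CD69 (ENSG00000110848) lies on chromosome 12 from 9752486 to 9760901, and FGFBP2 (ENSG00000137441) on chromosome 4 from 15960243 to 15969309. CX3CR1 (ENSG00000168329) lies on chromosome 3 from 39263494 to 39281735, and FCGR3A (ENSG00000203747) on chromosome 1 from 161541759 to 161550737.

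The same test called 3315 of 12872 genes, of which 1859 rose and 1456 fell, and 1064 of the rises and 391 of the falls were at least 2-fold. Among the 14 largest rises were NR4A1 (7.88 ± 0.28), FOSB (7.26 ± 0.39), FOS (6.48 ± 0.33) and JUN (5.78 ± 0.39), all transcription factors induced within minutes of a stimulus. Also among them were HSPA1B, a heat shock chaperone (6.17 ± 1.04), ITM2C, a membrane protein (5.53 ± 0.48), RGCC, a cell cycle regulator (5.39 ± 0.48), AREG, the growth factor amphiregulin (4.35 ± 0.52), and TNFAIP3, a brake on NF-kappaB (4.15 ± 0.27). HSPA1B was not called in donors 4 and 5 alone (4.77, adjusted p = 0.0600). The 14 largest falls included ASCL2, a transcription factor (-2.82 ± 0.37), AK5, an adenylate kinase (-2.54 ± 0.44), SPON2, a secreted matrix protein (-2.52 ± 0.34), PRSS23, a serine protease (-2.38 ± 0.31), and S1PR5, an egress receptor (-2.14 ± 0.37). PTGDS (-2.80 ± 0.65) and MYOM2 (-2.70 ± 0.60) also fell in all 5 donors, but the call for PTGDS ended without donor 2 (adjusted p = 0.0613) and without donor 4 (0.0585), and that for MYOM2 without donor 2 (0.0596) and in donors 4 and 5 alone (0.0799, at -0.96).

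**Figure D2:**
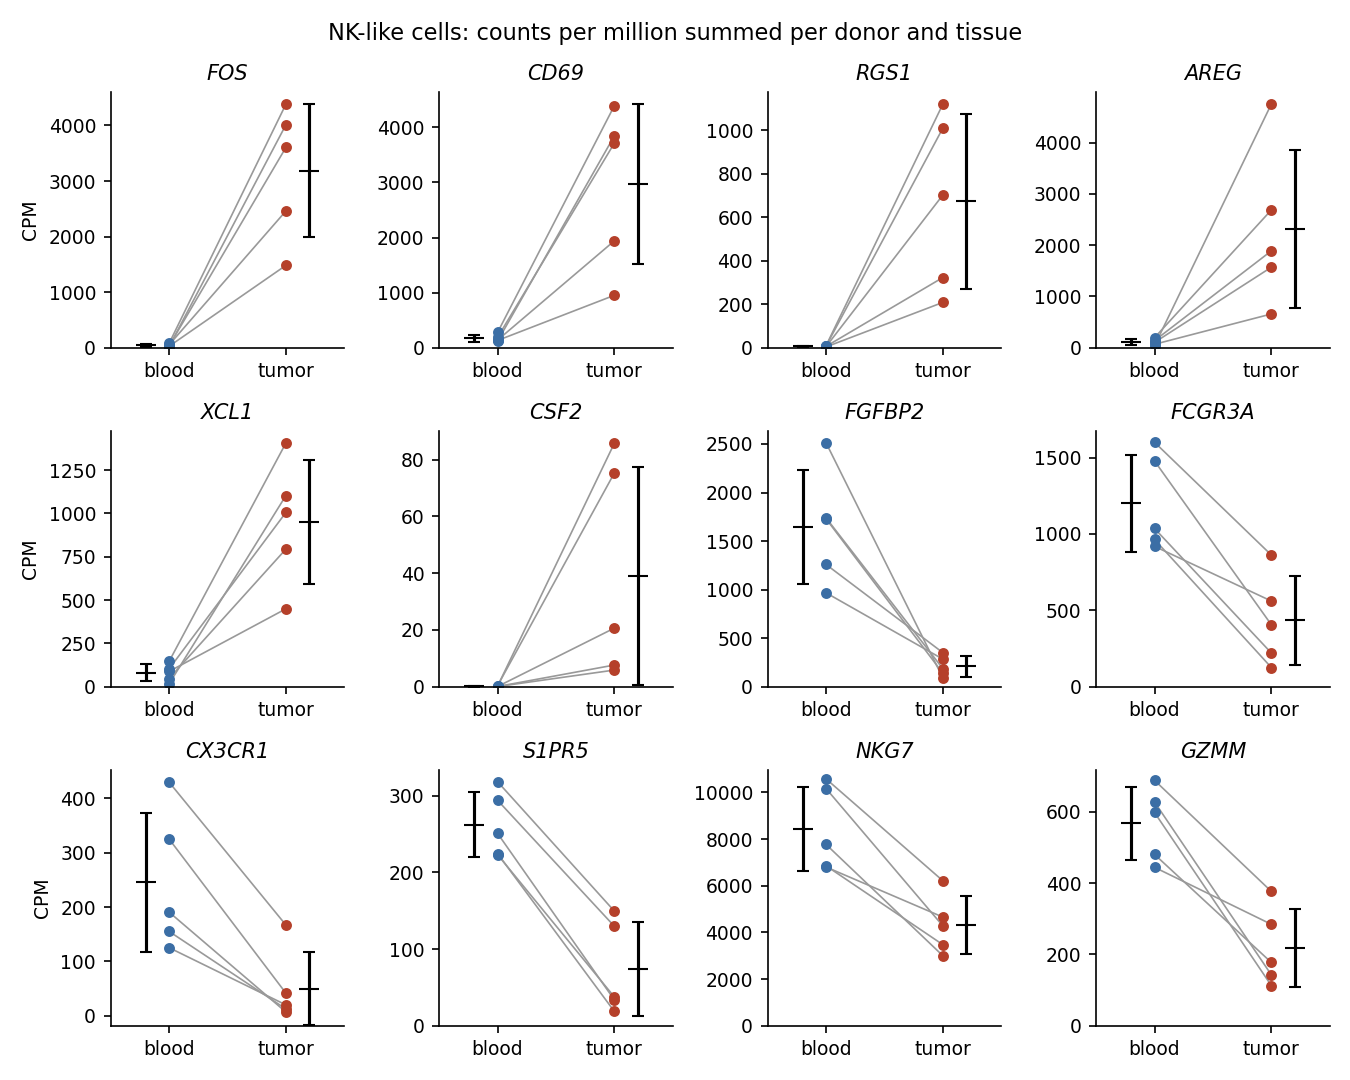
CPM of named genes in NK-like cells summed per donor, with lines joining blood and tumor of the same donor and bars for the mean and SD (n = 5). FGFBP2 fell from a mean of 1641 to 209 CPM, and it fell in all 5 donors.

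Within the annotation batches the test called 1391 genes in donors 1 to 3 and 1464 in donors 4 and 5. Without donor 2 it called 2114 genes and without donor 4 it called 2089, and with donors 1 and 5 both left out it called 2242. With equal numbers of cells of each class drawn from blood and tumor it called 1581, of which 1349 were among the 3315 and in the same direction, but it also used fewer cells. That fit drew more CD16-high than CD56-bright cells in every donor. In that fit the called members had a median of 0.982 of their log2 fold change for immediate-early genes, 0.946 for tissue residency genes, 0.585 for the CD16-high program, 0.530 for egress genes, 0.508 for activating receptors, 0.472 for cytotoxic genes, 0.439 for the CD56-bright program and 0.154 for 3 helper-like ILC markers.

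Gene groups fixed in advance showed which functions moved together. Of 22 immediate-early genes, 22 rose and 0 fell (camera adjusted p = 5.65e-90), and the call held with an estimated correlation (adjusted p = 0.00792). These genes took 0.211 ± 0.0619% of NK-like UMIs in blood and 1.83 ± 0.545% in tumor (SD, n = 5), and mitochondrial genes took 3.17 ± 0.850% and 2.49 ± 0.665%, lower in tumor in 5 of 5 donors. Of 14 heat shock genes, which encode protein-folding chaperones, 11 rose (7.51e-08), including HSPD1 (1.21 ± 0.11), HSP90AB1 (1.22 ± 0.13) and HSPE1 (1.38 ± 0.18). The adjusted p of the heat shock list was 0.229 with an estimated correlation. Only tumor had been dissociated with enzymes, and both groups are known to respond to handling.

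Of 18 NF-kappaB targets, 16 rose, among them NFKBIZ (3.87 ± 0.19) and NFKBID (2.86 ± 0.19), both regulators of the pathway itself (camera adjusted p = 1.04e-28, and 0.0124 with an estimated correlation). Of 9 chemokine ligands, 8 rose, including XCL1 (79.9 ± 49.95 to 951 ± 357 CPM, 3.84 ± 0.47) and XCL2 (2.64 ± 0.29), which attract dendritic cells, and CCL3L1 (2.95 ± 0.25), which attracts myeloid cells and lymphocytes (9.72e-08, and 0.033 with an estimated correlation). Of 16 secreted cytokines and growth factors, 10 rose, including TNF (4.13 ± 0.35), CSF1 (6.37 ± 0.54) and CSF2, which encodes GM-CSF (0.0799 ± 0.125 to 39.0 ± 38.5 CPM, 8.92 ± 0.27) (4.64e-13, and 0.0124 with an estimated correlation). The 1 that fell was TGFB1 (-0.39 ± 0.12), whose call ended on leaving out donor 2 (adjusted p = 0.0828), 3 (0.0941), 4 (0.119) or 5 (0.0629) and with an equal mix of classes (0.232). Of 16 genes of the TNF receptor family and co-stimulation, 10 rose, including TNFRSF18 (1.83 ± 0.16) and TNFRSF4 (1.82 ± 0.12), which co-stimulate lymphocytes, and 2 fell, TNFRSF14 (-0.60 ± 0.11) and TNFRSF1B (-0.93 ± 0.29) (4.11e-08, and 0.033 with an estimated correlation).

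Programs of NK cell subsets moved in opposite directions. Of 18 genes of the CD16-high circulating program, 17 fell and 0 rose, including CLIC3, a chloride channel protein (-1.61 ± 0.20), and TBX21, a transcription factor of cytotoxic maturation (-1.03 ± 0.13) (camera adjusted p = 2.05e-14). The adjusted p of this list was 0.16 with an estimated correlation. Of 18 genes of the CD56-bright program, 16 rose and 0 fell, including TCF7, a transcription factor of less mature lymphocytes (1.77 ± 0.14), CD44, an adhesion receptor (2.18 ± 0.19), and COTL1, an actin-binding protein (3.05 ± 0.30) (1.49e-15, with adjusted p = 0.16 with an estimated correlation). Markers that named clusters made up 10 and 14 of the genes of these lists. With each class matched in number between blood and tumor, mostly CD16-high cells, FCGR3A was lower by -0.69 and TCF7 higher by 0.45, against -1.62 and 1.77 in all NK-like cells.

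Of 18 tissue residency genes, 13 rose, including SPRY1, a signaling inhibitor (4.72 ± 0.26), ITGA1, an integrin that binds collagen (5.44 ± 0.52), and CD69 (camera adjusted p = 8.49e-15). The adjusted p was 0.127 with an estimated correlation. The 1 that fell was PRDM1 (-0.77 ± 0.24), a repressor, whose call ended without donor 1 (adjusted p = 0.0876), 4 (0.119) or 5 (0.131) and whose direction turned with an equal mix of classes (0.07). ITGAE, which encodes the residency integrin CD103, was not called (66.0 ± 7.87 and 57.6 ± 17.99 CPM). Of 14 egress and blood homing genes, 8 fell, including S1PR4 (-0.88 ± 0.12) and CXCR1 (-2.09 ± 0.31), and 2 rose, among them CCR7, a lymph node homing receptor (2.29 ± 0.60) (2.16e-04, with adjusted p = 0.167 with an estimated correlation).

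**Figure D3:**
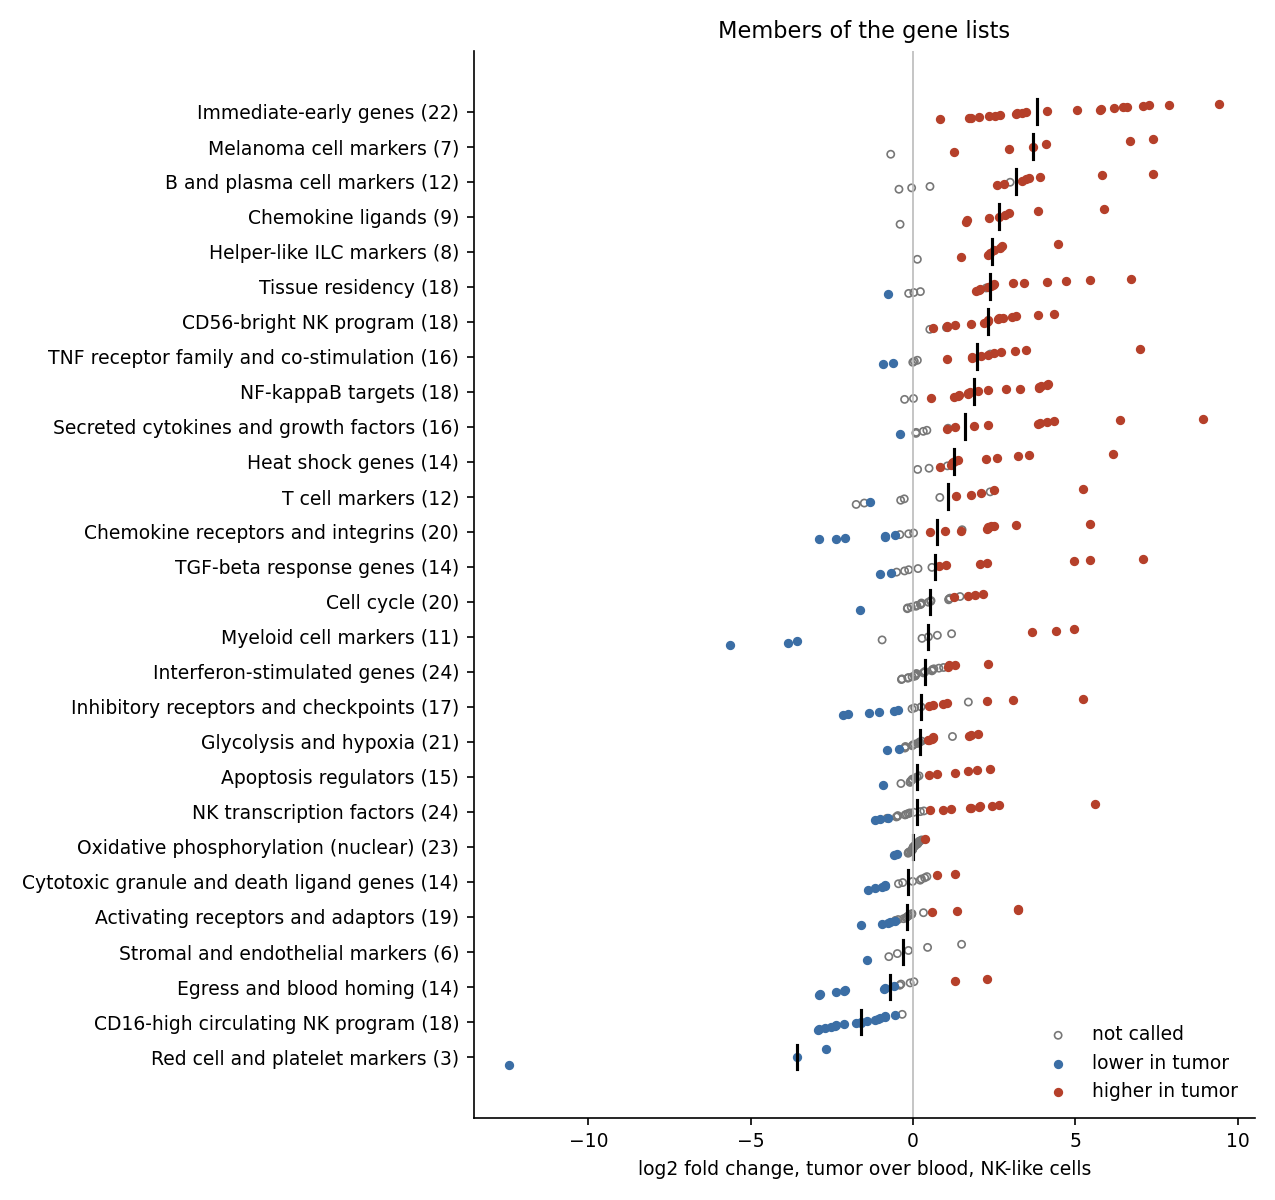
Log2 fold change (tumor over blood, NK-like cells) of each tested member of the 28 lists, filled where called, with a black line at the median and the number tested in brackets. All 22 immediate-early genes lay above 0, and 17 of 18 genes of the CD16-high program were called lower.

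Cytotoxic and receptor genes went both ways. Of 14 cytotoxic granule and death ligand genes, 5 fell: NKG7, a granule membrane protein (8434 ± 1817 to 4322 ± 1241 CPM, -0.88 ± 0.16), the granzymes GZMM (-1.39 ± 0.26) and GZMH (-1.18 ± 0.23), the pore former PRF1 (-0.86 ± 0.17) and CST7, a protease inhibitor (-0.95 ± 0.24). The 2 that rose were TNFSF10, the death ligand TRAIL (1.30 ± 0.25), and SRGN, a granule proteoglycan (0.73 ± 0.17) (camera adjusted p = 0.165). GZMB was not called (3584 ± 838 and 2485 ± 895 CPM). Of 19 activating receptors and adaptors, 4 rose (KLRK1, NCR2, KLRC2 and CRTAM) and 5 fell (NCR3, FCGR3A, SLAMF6, CD247 and CD160). CRTAM, an adhesion receptor, changed by 3.22 ± 0.48 and SLAMF6 by -0.70 ± 0.13, and for this list the median (-0.19) and the test (down, adjusted p = 0.392) differed in sign from the mean (0.11). Of 17 inhibitory receptors and checkpoints, 7 rose and 6 fell (0.73). ENTPD1, an enzyme that degrades extracellular ATP (3.06 ± 0.33), and CTLA4 (0.093 ± 0.0886 to 4.48 ± 5.07 CPM, 4 of 5 donors) rose, while SIGLEC7 (-1.34 ± 0.19) and KLRG1 (-1.06 ± 0.17), receptors of mature NK cells, fell. TIGIT (96.8 ± 57.9 and 109 ± 73.4 CPM) and PDCD1 (0.505 ± 0.815 and 2.02 ± 2.32 CPM) were not called. With an equal mix of classes the calls ended for GZMH (-0.36, adjusted p = 0.0568), KLRG1 (-0.41, 0.0528) and SLAMF6 (-0.28, 0.178), and that for SLAMF6 also ended with donors 1 and 5 left out (0.0535). In donors 1 to 3 alone GZMH (0.0730), SLAMF6 (0.0569), TNFSF10 (0.0641) and NKG7 (0.0797) were not called, nor was NKG7 in donors 4 and 5 (0.112).

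Of 24 NK transcription factors, 10 rose, including ID3, an inhibitor of E proteins (5.61 ± 0.40), and BHLHE40, a basic helix-loop-helix factor (2.06 ± 0.09), and 3 fell, TBX21, PRDM1 and ZEB2 (-1.18 ± 0.31) (camera adjusted p = 0.000918, with adjusted p = 0.229 with an estimated correlation). Of 14 TGF-beta response genes, 7 rose, including SKIL (2.28 ± 0.16), a feedback inhibitor of that pathway, and 2 fell, the receptors TGFBR3 (-1.01 ± 0.16) and TGFBR2 (-0.69 ± 0.19) (4.93e-07, with adjusted p = 0.16 with an estimated correlation). Of 20 chemokine receptors and integrins, 10 rose, including CXCR4, a homing receptor (219 ± 110 to 2105 ± 1429 CPM, 3.17 ± 0.33), and ICAM1, an adhesion ligand (2.32 ± 0.20), and 6 fell, including CX3CR1 (0.15). Of 24 interferon-stimulated genes, 4 rose, among them IFITM3 (1.08 ± 0.19), OAS3 (1.28 ± 0.40, 3 of 5 donors) and IFI44L (2.30 ± 0.70, 4 of 5 donors) (0.064). The call for IFI44L ended on leaving out donor 1 (adjusted p = 0.0787), 2 (0.127), 3 (0.0849) or 5 (0.111). With an equal mix of classes the calls ended for IFITM3 (0.26, adjusted p = 0.252) and IFI44L (1.25, 0.0596), and in donors 1 to 3 alone IFITM3 was not called (0.0501).

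Of 21 glycolysis and hypoxia genes, 8 rose, including HIF1A, the hypoxia factor (1.79 ± 0.13), SLC2A3, a glucose transporter (1.73 ± 0.23), and PFKFB3, an activator of glycolysis (2.00 ± 0.31), and 2 fell, BNIP3 (-0.81 ± 0.22) and PGAM1 (-0.42 ± 0.13) (camera adjusted p = 0.027, with adjusted p = 0.442 with an estimated correlation). The call for BNIP3, a mitophagy gene, ended without donor 2 (adjusted p = 0.0838), 4 (0.0855) or 5 (0.0522). Of 23 nuclear genes of oxidative phosphorylation, 2 fell, NDUFB7 (-0.58 ± 0.09) and NDUFB2 (-0.51 ± 0.13), and 1 rose, COX7C (0.37 ± 0.10, 4 of 5 donors) (0.773, direction down although the median and mean were 0.01). Without donor 2 the calls for NDUFB2 (adjusted p = 0.072) and COX7C (0.0689) ended, and without donor 4 they also ended (0.0582 and 0.1), as did COX7C without donor 3 (0.0815) or 5 (0.0908). Of 15 apoptosis regulators, 6 rose, including PMAIP1 (2.37 ± 0.30) and BCL2L11 (1.28 ± 0.21), which promote death, and MCL1 (111 ± 39.8 to 459 ± 312 CPM), which opposes it, and 1 fell, the survival gene BCL2L1 (-0.93 ± 0.17) (0.0729). Of 20 cell cycle genes, 4 rose, TYMS (1.90 ± 0.34), CENPF (2.15 ± 0.42), CDK1 (1.70 ± 0.40) and TK1 (1.25 ± 0.36, 4 of 5 donors), and 1 fell, RRM2 (-1.63 ± 0.40) (0.07). The cluster led by TYMS and MKI67 had been left unnamed and was not in these sums, the call for CDK1 ended without donor 2 (adjusted p = 0.0529) and with DESeq2 (0.0517), and that for RRM2 without donor 5 (0.0672). With an equal mix of classes the calls ended for BCL2L1 (-0.24, adjusted p = 0.210), BNIP3 (-0.36, 0.190), NDUFB2 (-0.29, 0.0903), COX7C (0.24, 0.120), CENPF (1.46, 0.0570) and RRM2 (-0.67, 0.289).

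Markers of other cell types were also read in NK-like cells. Of 12 B and plasma cell markers, 8 rose, including IGKC, the kappa light chain (1.43 ± 2.13 to 68.6 ± 69.1 CPM), MZB1 (2.60 ± 0.15) and DERL3 (3.90 ± 0.54), both of the secretory pathway (camera adjusted p = 9.95e-07, with adjusted p = 0.16 with an estimated correlation). Of 7 melanoma cell markers, 6 rose, all at low levels, such as SERPINE2, a protease inhibitor (5.55 ± 2.35 to 12.6 ± 4.81 CPM), and APOE, a lipid carrier (0.0304 ± 0.0437 to 6.36 ± 6.47 CPM) (1.29e-04, with adjusted p = 0.176 with an estimated correlation). In CD56-bright cells SERPINE2 went from 16.9 ± 12.5 CPM in blood to 10.7 ± 4.27 in tumor. MZB1 went there from 11.3 ± 9.18 to 11.8 ± 6.38 CPM, so blood NK-like cells of that class already held both. In CD16-high cells SERPINE2 went from 4.92 to 15.6 CPM and MZB1 from 1.94 to 17.8 CPM. Of 8 helper-like ILC markers, 7 rose, including LTB, a TNF family ligand (76.7 ± 27.5 to 381 ± 216 CPM), and IL23R, a cytokine receptor (0.162 ± 0.131 to 1.23 ± 1.15 CPM) (1.34e-04, with adjusted p = 0.16 with an estimated correlation). Of 12 T cell markers, 5 rose (CD28, TRAC, ICOS, CTLA4 and TRAT1) and 1 fell, BCL11B (0.159), whose call ended without donor 4 (adjusted p = 0.0619) and with an equal mix of classes (0.143). TRAC, the T cell receptor alpha constant gene, went from 43.1 ± 19.4 to 112 ± 80.4 CPM. Of 11 myeloid markers, 3 rose (C1QA, C1QB and CLEC9A) and 3 fell (S100A8, S100A9 and FCN1), and the highest of these was S100A9 with 3.07 ± 2.77 CPM in blood (0.968). CLEC9A was not called by DESeq2 (adjusted p = 0.0525).

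Of 6 stromal and endothelial markers, 1 fell, IGFBP7 (-1.42 ± 0.22), which also stands in the CD16-high program (camera adjusted p = 0.308). The 3 tested red cell and platelet markers all fell (5.47e-05, with adjusted p = 0.16 with an estimated correlation). They were HBB (577 ± 1280.3 to 0.0901 ± 0.161 CPM), HBA2 (123 ± 175 to 11.7 ± 17.7 CPM) and HBA1 (225 ± 286 to 31.2 ± 48.4 CPM), which encode hemoglobin chains. An NK-like cluster led by PTGDS and MYOM2 held HBA1 and HBA2 together at 1062 CPM and HBB at 3.53 CPM. HBA1 and HBA2 thus did not always come with HBB, so their fall is not read as a loss of red cell RNA. HBB rested on blood library 5 (2868 CPM, with 13.5 CPM or less in the other blood sums) and was not called by DESeq2 (adjusted p = 0.14). The call for HBA1 ended without donor 2 (adjusted p = 0.115), 3 (0.0691), 4 (0.0659) or 5 (0.0987) and with an equal mix of classes (0.0975).

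Adjusted over the list alone, the counts of risen and fallen members were 22 and 0 for immediate-early genes, 13 and 0 for heat shock, 16 and 0 for NF-kappaB targets, 8 and 0 for chemokine ligands and 10 and 1 for cytokines. Adjusted over the list alone they were 11 and 2 for the TNF receptor family, 0 and 17 for the CD16-high program, 17 and 0 for the CD56-bright program, 14 and 1 for residency, 2 and 8 for egress, 2 and 6 for cytotoxic genes, 5 and 6 for activating receptors and 7 and 6 for inhibitory receptors. The other lists, adjusted over the list alone, gave 10 and 3 for transcription factors, 8 and 3 for TGF-beta, 11 and 6 for chemokine receptors and integrins, 2 and 0 for interferon, 9 and 2 for glycolysis, 0 and 2 for oxidative phosphorylation, 6 and 2 for apoptosis and 4 and 1 for cell cycle. For markers of other cells, adjusted over the list alone, they were 9 and 1 for B and plasma cells, 6 and 0 for melanoma, 7 and 0 for ILC, 6 and 2 for T cells, 3 and 3 for myeloid, 0 and 1 for stromal and 0 and 3 for red cells. Camera called 17 of the 28 lists at the preset correlation (22 in donors 1 to 3 and 16 in donors 4 and 5) and 5 with an estimated correlation: immediate-early genes, NF-kappaB targets, cytokines, chemokine ligands and the TNF receptor family. Fry, which asks only whether members move 1 way on balance, called 19.

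The next comparisons asked whether tumor and blood also differed inside each class of NK-like cell. In CD16-high cells, the cytotoxic class that dominates blood, ITM2C rose by 8.08 ± 0.32 from 0.441 ± 0.177 to 131 ± 121 CPM, and RGS1 by 7.04 ± 0.28 from 5.41 ± 2.04 to 784 ± 462 CPM (SD, n = 5, each with adjusted p = 1.76e-07). FOSB (7.04 ± 0.36), FOS (6.61 ± 0.33), HSPA1B (6.26 ± 0.83) and ATF3, a stress-induced transcription factor (5.96 ± 0.49), also rose. FGFBP2 fell by 1.88 ± 0.27 from 1764 ± 577 to 483 ± 222 CPM (adjusted p = 0.00128). MYOM2 (-2.22 ± 0.31), ASCL2 (-1.79 ± 0.26), CX3CR1 (-1.74 ± 0.31), CHST2, a sulfotransferase (-1.59 ± 0.19), and SPON2 (-1.53 ± 0.27) also fell. Each of these 12 genes moved the same way in 5 of 5 donors, but in donors 4 and 5 alone MYOM2 stood at -0.78 and was not called (adjusted p = 0.383).

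In CD16-high cells edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2101 of 12093 genes, 1195 higher and 906 lower in tumor. Chemokine ligands rose in 7 of 7 tested, cytokines in 12 of 16, tissue residency genes in 14 of 18 and immediate-early genes in 22 of 22. The CD16-high program fell in 16 of 18 genes and egress genes in 9 of 14, whereas 1 egress gene, CCR7, rose. Heat shock genes rose in 13 of 14, B and plasma cell markers in 4 of 8 (MS4A1, IGKC, IGHG1 and MZB1) and melanoma markers in 4 of 5 (PMEL, S100A1, APOE and SERPINE2). Donors 1 to 3 gave 1324 calls, donors 4 and 5 gave 519, leaving out donor 2 gave 1226 and leaving out donors 1 and 5 gave 1252. A cluster led by CCL3, HSPA6, IFNG and CD69, which gave this class 3216 tumor cells, scored 0.755 for CD16-high and 0.742 for CD56-bright markers, so its class was nearly tied. CCL3 and CCL4, both CD16-high naming markers, were among its leading genes, so chemokine genes helped to place it in this class. The rise of chemokine ligands in CD16-high cells is therefore not independent of the naming.

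In CD56-bright cells, the class of cytokine-producing NK cells, NR4A1, a nuclear receptor induced by activation, rose by 7.45 ± 0.32 from 1.64 ± 2.44 to 173 ± 174 CPM (adjusted p = 1.33e-12), and JUN by 5.57 ± 0.29 (SD, n = 5). EGR1 had 0 counts among 4754989 UMIs of the 5 blood sums and 5451 counts in tumor, which made it at least 301-fold higher against a floor of 3 counts over the group. HSPA1B (6.74 ± 0.60), FOSB (6.49 ± 0.28) and NR4A2 (5.73 ± 0.23) also rose. FGFBP2 fell by 1.87 ± 0.25 from 129 ± 41.9 to 31.1 ± 13.98 CPM (adjusted p = 3.4e-05). SPON2 (-1.48 ± 0.29), FUT7, a fucosyltransferase of selectin ligands (-1.28 ± 0.22), RASGRP2, an activator of integrin signaling (-1.05 ± 0.21), CEP78, a centrosomal gene (-1.02 ± 0.15), and GZMM (-0.94 ± 0.18) also fell, each of the 12 named genes in 5 of 5 donors.

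In CD56-bright cells edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 750 of 9636 genes, 512 higher and 238 lower in tumor. Immediate-early genes rose in 21 of 21 tested, NF-kappaB targets in 16 of 18, heat shock genes in 12 of 14, chemokine ligands in 6 of 7 and residency genes in 8 of 18. The CD16-high program fell in 13 of 18 genes, while the CD56-bright program rose in 4 (XCL1, XCL2, CD44 and AREG) and fell in 2 (LEF1 and IL18R1) of 18. The 4 that rose are also markers that named this class. Of 7 B and plasma cell markers 2 rose (IGKC and IGHG1), and of 3 melanoma markers 1 rose (APOE). DESeq2 called 445 genes and did not call SPON2 (adjusted p = 0.189), thinning to the smallest sum (60 cells) gave 226 and did not call FUT7 (-0.73, 0.204) or RASGRP2 (-0.83, 0.108), and leaving out donor 5 gave 396. Donors 1 to 3 gave 329 calls, without GZMM (adjusted p = 0.0604), donors 4 and 5 gave 679, and leaving out donors 1 and 5 gave 331.

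Of 9586 genes tested in both classes, 418 rose in both (52.9 by chance if calls were independent), 162 fell in both (19.5 by chance) and 4 were called in opposite directions: TIMP1 and DOCK5 fell in CD16-high and rose in CD56-bright cells, and CHPT1 and CRIP2 did the reverse. The classes are different cells of the same donors, so this overlap also carries whatever the tissues of a donor share. The clusters that hold each class also differed between blood and tumor.

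**Figure D4:**
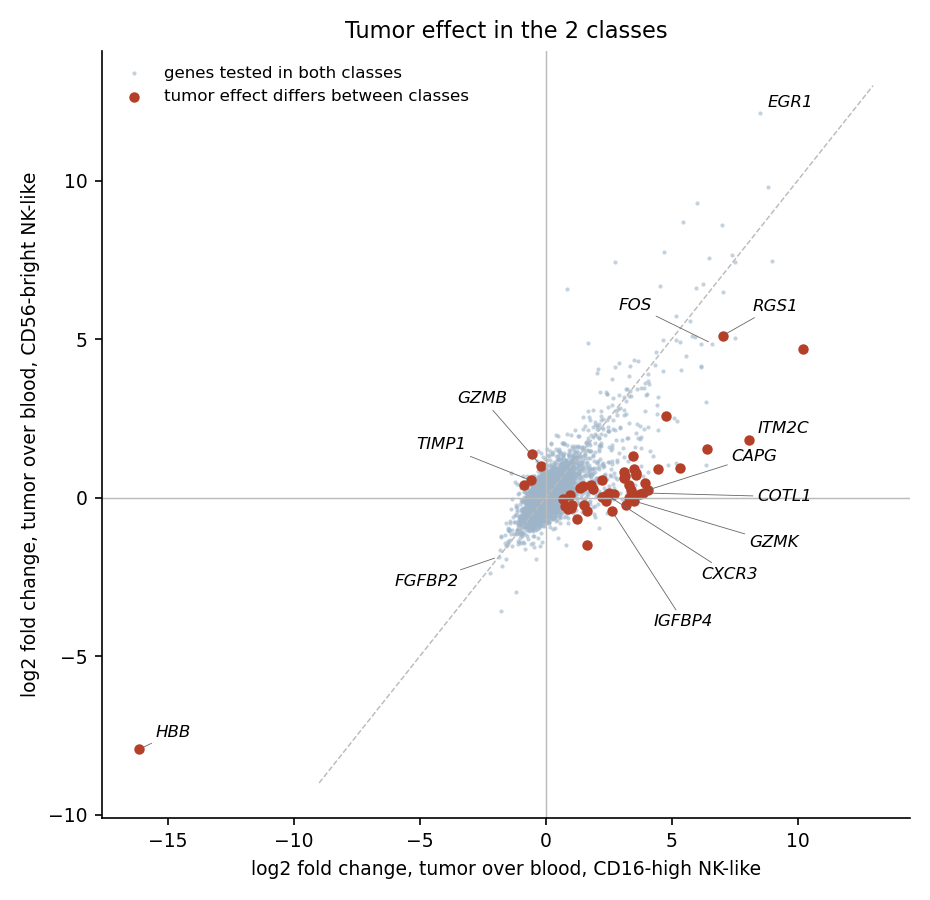
Log2 fold change (tumor over blood) in CD16-high cells against CD56-bright cells for 9586 genes tested in both, with genes whose tumor effect differed between classes in red and a dashed line of equal effect. ITM2C, CAPG, COTL1 and GZMK lay far to the right of that line, and EGR1, at 0 counts in CD56-bright blood, is drawn at its fitted value.

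The last test asked for which genes the tumor effect itself differed between the classes. ITM2C rose more in CD16-high cells, with a difference in log2 fold change of 6.21 ± 0.48 (SE, n = 5, adjusted p = 3.32e-06), and went from 24.8 ± 15.4 to 95.7 ± 57.7 CPM in CD56-bright cells. CAPG, an actin-capping protein (3.82 ± 0.45), COTL1 (3.69 ± 0.50), GZMK, a granzyme of CD56-bright cells (3.61 ± 0.47), IGFBP4, a binding protein of insulin-like growth factors (2.91 ± 0.51), and CXCR3, a chemokine receptor (2.38 ± 0.41), were likewise higher in that contrast in 5 of 5 donors. GZMK went from 78.8 ± 61.1 to 748 ± 220 CPM in CD16-high cells and from 834 ± 169 to 762 ± 205 CPM in CD56-bright cells. GZMB, the main granzyme of cytotoxic cells (-1.21 ± 0.15), and TIMP1, a protease inhibitor (-1.15 ± 0.21), differed the other way in 5 of 5 donors. GZMB went from 3798 ± 829.1 to 3271 ± 893 CPM in CD16-high cells and from 1140.4 ± 601 to 2127 ± 855 CPM in CD56-bright cells.

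The interaction called 55 of 11650 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 50 above 0 and 5 below (HBB, DOCK5, CATSPER1, GZMB and TIMP1). HBB stood at 661 ± 1468 CPM in blood CD16-high cells and 0 in tumor. Only 1 donor lay below 0 in that contrast for HBB and 2 lay above, so its call has no shared direction. All 50 genes above 0 were called higher in tumor CD16-high cells, and 15 of the 50 were called in CD56-bright cells in either direction. In the CD56-bright program 5 of 18 genes passed (GZMK, COTL1, CAPG, CXCR3 and CD27; 12 adjusted over the list alone), whereas the median difference was -0.16 over 22 immediate-early genes and 0.06 over 14 heat shock genes. Calls CAPG, COTL1, GZMK, CXCR3 and GZMB are also markers that named the classes, and the nearly tied cluster with 3216 tumor cells bears on all of them. The count was 41 in donors 1 to 3, 1 in donors 4 and 5, 103 with DESeq2, and 27, 27, 23, 10 and 75 without donors 1 to 5. CXCR3 (adjusted p = 0.0505, 0.0614 and 0.0862 without donors 1, 2 and 4), IGFBP4 (0.053, 0.0525 and 0.156 without donors 1, 3 and 4) and TIMP1 (0.0677, 0.0996, 0.0818 and 0.0587 without donors 2 to 5) did not hold in every fit that left out 1 donor, nor did IGFBP4 (0.0896) and TIMP1 (0.185) with thinned sums. In donors 1 to 3 GZMB (-1.08, adjusted p = 0.0659) and TIMP1 (-1.27, 0.254) were not called, and in donors 4 and 5 only ITM2C of the 8 named genes was, with GZMB at -1.39 (0.0906), TIMP1 at -1.01 (0.279), CAPG at 2.76 (0.0726), GZMK at 2.65 (0.0818), COTL1 at 2.35 (0.468), IGFBP4 at 1.84 (0.468) and CXCR3 at 1.60 (0.510).

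The 3 regions of the tumor of donor 5 were compared as single libraries, with no replicate and no test. AREG stood at 983 CPM in NK-like cells of the nodule (Poisson 95% interval 958 to 1007) and 389 CPM in the center (373 to 405), a ratio of 2.53. IRF4, a transcription factor of activated lymphocytes, stood at 18.6 CPM in the nodule (15.4 to 22.3) and 6.33 in the center (4.44 to 8.77), and IL7R, the interleukin-7 receptor, at 426 in the nodule (410.1 to 443) and 209 in the cortex (196 to 224). CXCR6, a receptor of tissue lymphocytes, was highest in the center at 67.2 CPM (60.6 to 74.3) and lowest in the nodule at 24.2 (20.5 to 28.3). CCL3, a chemokine, was also highest in the center at 1071 CPM (1044 to 1098) and lowest in the nodule at 614 (595 to 634), and ITGA1 was highest in the cortex at 10.1 CPM (7.26 to 13.6) and lowest in the center at 5.28 (3.56 to 7.54).

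**Figure D5:**
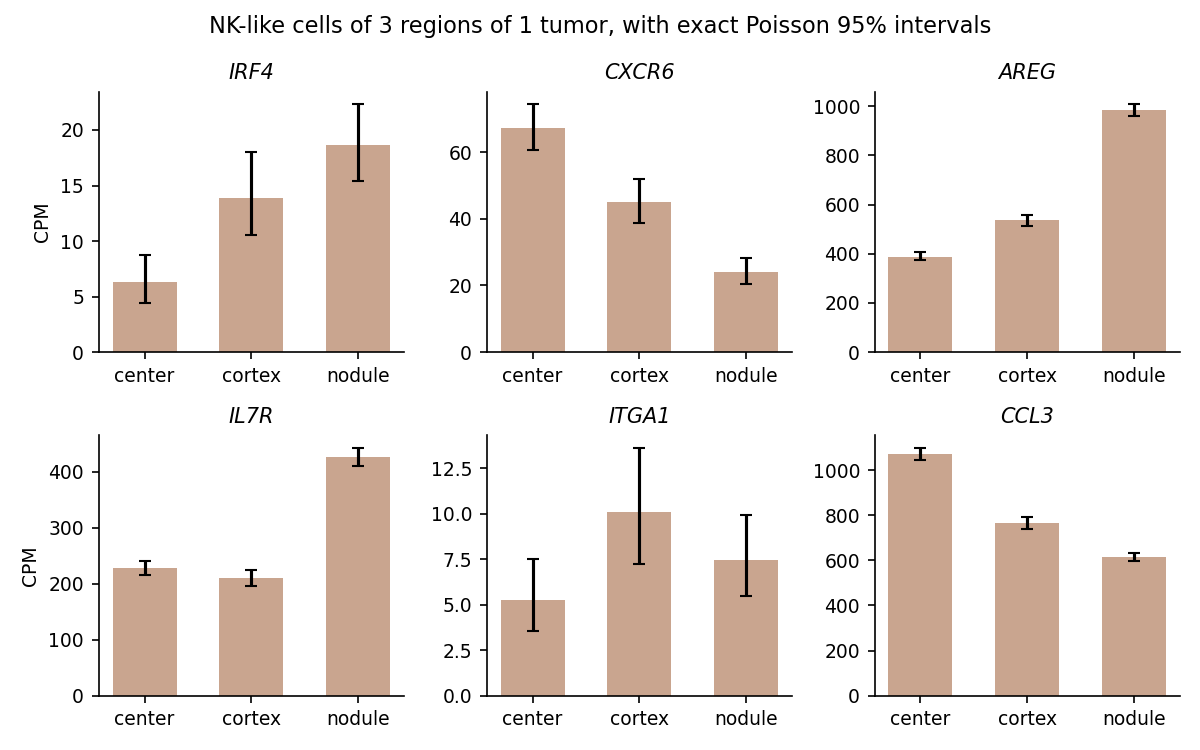
CPM of 6 genes in NK-like cells of the center, cortex and nodule of 1 tumor, 1 library each, with exact Poisson 95% intervals for counting error. AREG ranged from 389 CPM in the center to 983 CPM in the nodule.

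These values came from 1058, 666 and 1006 NK-like cells with 5683506, 4170653 and 6287780 UMIs in center, cortex and nodule. Among 70 list members with at least 100 counts the median ratio of the highest to the lowest region was 1.33, and 4 reached 2, a bound set after the ratios had been seen. Regions differed in their mix of classes, with 411 of 1058 cells CD56-bright in the center, 303 of 666 in the cortex and 605 of 1006 in the nodule (41.6%, 49.1% and 63.2% of UMIs). These shares of UMIs alone could raise a gene of that class by at most 1.52 between center and nodule and 1.29 between cortex and nodule, less than the ratios of AREG and IL7R. Within CD56-bright cells AREG stood at 725 CPM in the center (691 to 759.9) and 1427 CPM in the nodule (1390.3 to 1465), and IL7R at 423 CPM in the cortex (395 to 452) and 665 CPM in the nodule (639.7 to 691). IRF4 stood in CD16-high cells at 33.3 CPM in the nodule (26.3 to 41.6), 14.1 in the cortex (9.54 to 20.2) and 7.83 in the center (5.12 to 11.5), and in CD56-bright cells at 10.1 in the nodule (7.19 to 13.7), 13.7 in the cortex (9.08 to 19.7) and 4.23 in the center (2.03 to 7.78). CXCR6 was highest in the center in both classes, at 103 CPM against 48.5 in the nodule in CD16-high cells (92.4 to 115 and 39.9 to 58.3) and 16.9 against 10.1 in CD56-bright cells (12.1 to 23.04 and 7.19 to 13.7). In CD16-high cells AREG was highest in the cortex at 251 CPM (230 to 274), with 217 in the nodule (199 to 237) and 150 in the center (137 to 163). CCL3, whose ratio of 1.74 lay near the 1.59 that the shares alone could give, stood at 1801 CPM in the center and 1482 in the nodule in CD16-high cells (1756 to 1848 and 1433 to 1532) and, the other way, at 45.7 and 110 CPM in CD56-bright cells (37.5 to 55.2 and 99.8 to 121).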

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

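The test of melanoma markers without S100B, the tests of class mix on the 2 programs, the weight given to splits that part all pairs, the bounds for searching single values and the interaction genes listed below were chosen after results had been seen. Genes of NK-like cells that moved between tumor and blood were weighed against chance, class mix, handling and RNA from other cells.

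Chance as the source of the gene counts was tested on other splits of the same 10 sums. Of 100 splits, 1 (the real one) called as many genes as the 3315 in NK-like cells, the 2101 in CD16-high cells and the 750 in CD56-bright cells, and the highest others called 416, 301 and 197. The highest others parted 3 of the 5 donor pairs, and with donor as a block such splits estimate the effect from fewer donors, so they are no fair comparison. Among the 14 splits that part all 5 pairs, as the real one does, the highest others gave 0, 0 and 6 genes, but 14 are too few for a share under 0.05. For the interaction, 1 of the 16 sign flips (the real one, 55 genes) was as large and the highest other gave 0, and 16 are too few as well.

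Part of the change in tumor NK-like cells could come from a different mix of CD16-high and CD56-bright cells. Cells of each named class were drawn in equal numbers from both tissues. For donors 1 to 5 this drew 1310, 973, 610, 627 and 1411 CD16-high cells per tissue, of 1435, 1159, 670, 1129 and 1730 cells. The fit therefore gives the CD16-high class more weight. Log2 fold changes then had a median of 0.708 of their size over 2918 called genes (quartiles 0.509 and 0.908). The median was 0.585 over 17 called genes of the CD16-high program (0.531 and 0.672) and 0.439 over 16 of the CD56-bright program (0.225 and 0.585). Drawing per name matches the class mix between tissues only if the names hold. The nearly tied cluster led by CCL3, HSPA6, IFNG and CD69 gave 1238 of 1310 tumor CD16-high cells in donor 1 and 945 of 973 in donor 2. It gave 494 of 610 in donor 3 and 510 of 627 in donor 4. If that cluster holds both classes the test cannot decide, so class mix stays open for each of these groups. RGS1 stood at 6.31 and EGR1 at 8.73 in that fit, against 6.70 and 9.43, while FGFBP2 (-1.86 against -2.94), CX3CR1 (-1.68 against -2.90) and COTL1 (1.53 against 3.05) lost part of their change and FCGR3A (-0.69 against -1.62) and TCF7 (0.45 against 1.77) stood below 0.5 of theirs. Of the 3315 genes 1349 were still called in the same direction with fewer cells. The class of the nearly tied cluster is unsettled, so a shift in class stays open as part or all of the cause for genes that differ between the classes.

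Immediate-early and heat shock genes such as EGR1, FOS and HSPA1B may have risen in the tumor itself or while tissue was dissociated with enzymes, which blood never was. Handling that acts on all cells predicts a rise in both classes. The called members of both lists had medians above 0 in each class, with the lowest median 1.26 (heat shock in CD56-bright cells), and 3.72 and 3.70 for immediate-early genes in CD16-high and CD56-bright cells. These members had been chosen by their rise in the pooled sums of the same classes, which made medians above 0 likely in advance. The value meets what handling predicts, but activation in the tumor predicts it as well. Dissociation and tissue cannot be told apart here, because every tumor library had been dissociated and no blood library had, and this holds for CD69, TNFAIP3, CCL3 and IFNG too, which activation also induces.

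Immunoglobulin and melanoma transcripts in tumor NK-like cells could be free RNA from plasma cells and melanoma cells, which predicts a similar share of UMIs in NK-like and other cells of the same tumor. For IGKC, IGHG1, IGHM and JCHAIN the median ratio over 5 donors was 0.486 (0.00711, 0.613, 0.844, 0.486 and 0.00428 in donors 1 to 5), just under the lower bound of 0.5 and spread widely, so the test did not decide. For 5 melanoma markers it was 1.36, but S100B, at 103 CPM in blood NK-like cells, is made by NK-like cells and voids that test. Without S100B, with PMEL, MLANA, APOE and GPNMB left, it was 0.925 (0.121, 1.69, 0.925, 1.00029 and 0.743), but these ratios rest on 29, 4, 13, 15 and 1 counts in the other cells and the first lies far below the lower bound, so this test did not decide either. Low-level expression by NK-like cells was not tested, and the gate had kept only CD45-positive cells. SERPINE2 and MZB1 were outside these tests, and stood at 16.9 and 11.3 CPM in blood CD56-bright cells.

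Single values were searched with Dixon's test among the 5 donors of each group for genes, and among the 5 blood or 7 tumor libraries for totals, depth, mitochondrial share, cells and NK-like share, which by chance finds about 1 in 20 groups. It found 29 values in 248 groups, and 37 in 277 before genes of low level and of known copy number variation were set aside. For independent groups of normal values 12.4 would be expected among the 248. CPM was searched without a log transform and the groups share donors, so 12.4 is a rough guide only. Every gene value found stood above the others, as skewed values can give. Of the 27 found in gene values, 17 belonged to donor 5, 5 to donor 4, 2 to donor 3, 3 to donor 2 and 0 to donor 1. The other 2 were the NK-like share of blood library 5 (34.1%, next 81.6%) and the total of the tumor library of donor 4 (2.08097e+07 UMIs, 7 libraries). The 7 libraries include 3 regions of donor 5, which together held 2.09862e+07 UMIs, so donor 4 did not stand above the other 4 donors.

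Donor 5 stood above the other donors in blood NK-like cells for TNFAIP3 (64.4 CPM), TBX21 (418), TCF7 (47.5), BHLHE40 (78.1), TGFBR3 (149.5), RRM2 (14.1), TNFRSF14 (175) and HBB (2868). In tumor NK-like cells donor 5 stood above the others for CX3CR1 (167), TBX21 (278), CXCR1 (9.97), NR4A3 (115), BHLHE40 (310.2), TGFBR3 (102), TNFSF9 (73.2) and TNFRSF14 (132), and in blood CD56-bright cells for CEP78 (152). Donor 4 stood above the others for FUT7 in blood CD56-bright cells (287), for IFI44L (336) and IGFBP7 (618) in blood NK-like cells, and for S1PR4 (124) and HBA1 (116) in tumor NK-like cells. Donor 3 stood above for PTGDS in blood (1591) and CRTAM in tumor (249.8), and donor 2 for TNF (2.65) and IGKC (5.21) in blood and ITGA1 in tumor (74.0). TBX21, BHLHE40, TGFBR3 and TNFRSF14 were high in donor 5 in both tissues, so their paired change did not rest on that donor's level alone.

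Of the 55 genes whose tumor effect differed between the classes, the 8 that the rule named were ITM2C (6.21), CAPG (3.82), COTL1 (3.69), GZMK (3.61), IGFBP4 (2.91), CXCR3 (2.38), GZMB (-1.21) and TIMP1 (-1.15). The 843 ILC-like tumor cells entered none of the main comparisons and are described among the other observations.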

How the results depend on the processing

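The equal mix of classes, the fit without donors 1 and 5, the added cluster led by HBA2, KLRC2 and CD3G, and the depth of 2000 UMIs were tests chosen after results had been seen. The 110 genes named in NK-like cells gave 2577 values under the other settings: 2401 kept call and direction, 173 lost the call and 3 turned. For CD16-high cells 237 of 240 kept it, for CD56-bright cells 232 of 240 and for the interaction 134 of 160. The 3 that turned were PRDM1 (0.0660) with an equal mix of classes, and RRM2 with all cells passing the filters (0.75) and with no cell filter (0.77), settings that added every other cell type. Of the other named genes 33 lost the call with all cells and 32 with no cell filter. With an equal mix of classes 14 lost it (BCL11B, BCL2L1, BNIP3, CENPF, COX7C, GZMH, HBA1, IFI44L, IFITM3, KLRG1, NDUFB2, RRM2, SLAMF6 and TGFB1). In donors 1 to 3 it was 13 (BCL11B, BNIP3, COX7C, GZMH, HBA1, IFITM3, NDUFB2, NKG7, PRDM1, SLAMF6, TGFB1, TNFSF10 and TYMS), and in donors 4 and 5 it was 11 (CDK1, CENPF, COX7C, HSPA1B, IFI44L, MYOM2, NDUFB2, NDUFB7, NKG7, TGFB1 and TNFRSF14).

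In NK-like cells, with 3315 genes called, all cells passing the filters gave 1516, no cell filter 1653, donors with 33538 genes 1464, donors with 33694 genes 1391, an equal mix 1581, and calls of at least 2-fold 1455. DESeq2 gave 2925. Leaving out 1 donor gave 2089 (donor 4) to 2855 (donor 1), with 2020 to 2651 of the 3315 among them. In CD16-high cells (2101) thinning the sums gave 1313, the 33538-gene donors 519, the 33694-gene donors 1324, donors 1 and 5 left out 1252, calls of at least 2-fold 813, and leaving out 1 donor 1226 (donor 2) to 1718 (donor 5). In CD56-bright cells (750) DESeq2 gave 445, thinning 226, the 33694-gene donors 329, donors 1 and 5 left out 331, calls of at least 2-fold 351, and leaving out 1 donor 396 (donor 5) to 778 (donor 3). For the interaction (55) DESeq2 gave 103, no low-count filter 269, thinning 16, the 33538-gene donors 1, and leaving out 1 donor 10 (donor 4) to 75 (donor 5). Of the 28 gene lists, 17 were called, against 5 with an estimated correlation and 16 to 20 with 1 donor left out.

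With no block for the donor pairing, 980 genes were called in NK-like cells, 404 in CD16-high cells, 116 in CD56-bright cells and 9 for the interaction. Within a donor, blood and tumor deviations correlated at 0.361 to 0.862, each above the highest with another donor.

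Between the regions, AREG (2.18), IL7R (1.66) and CCL3 (1.97) with all cells, and CCL3 (1.90) with cells thinned to 2000 UMIs, moved from ratios of 2.53, 2.04 and 1.74.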

Other observations

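The values for ILC-like and T-like cells were chosen after the clusters had been seen, and none was tested. ILC-like cells of the tumors (843 cells, pooled) were named by markers that include KIT, IL23R, LTB and TNFSF11. High values of these genes are therefore no separate support for the name. KIT, a growth factor receptor of ILC precursors, stood at 88.4 CPM (Poisson 95% interval 77.9 to 100), against 5.35 CPM in tumor NK-like cells. IL23R, a receptor that drives ILC3, stood at 60.0 against 1.32 CPM. AREG, a tissue repair factor, stood at 4084 against 2009 CPM, LTB, which organizes lymphoid tissue, at 1800.2 against 387 CPM, TNFSF11, a TNF family ligand, at 98.8 against 13.1 CPM, and CSF2 at 149 against 54.2 CPM. Several NK cell genes were low: EOMES at 21.2 against 137 CPM, TBX21 at 6.59 against 145 CPM and FCGR3A at 11.4 against 399.8 CPM. The killing genes GZMB (150.5 against 2355 CPM) and PRF1 (130.04 against 1378 CPM) were low too. XCL1 went the other way, at 1395 against 1086 CPM. FCGR3A, GZMB, PRF1 and XCL1 are markers that named NK-like cells, whereas EOMES, TBX21 and CSF2 named no cluster. IL22, a cytokine of ILC3, had 0 counts (upper bound 1.28 CPM). These cells made up 2.37% to 8.06% of the cells of each tumor library, within a gate that took CD56-positive cells. The name depended on the resolution of the clusters. At the lower Leiden resolution no cluster was named ILC-like. SPINK2 and SPRY1, among the leading genes of the ILC-like cluster, then stood among those of a cluster named NK-like and CD56-bright. That cluster scored 0.800 for NK-like and 0.782 for ILC-like markers, so its name was nearly tied.

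T-like cells of the tumors (666 cells, 643 of them in tumor library 1) had transcripts of regulatory T cells. FOXP3, which sets that fate, stood at 259.6 CPM, with the checkpoint CTLA4 at 751, the co-stimulator ICOS at 454 and TNFRSF4 at 1419.9 CPM. FOXP3 was detected in 369 of 643 T-like cells of tumor library 1 (57.4%) and in 6 of 1639 NK-like cells of that library (0.366%). In blood library 5 it was detected in 92 of 2831 T-like cells (3.25%). The gate excluded CD3 and CD4, so these are cells that passed it in single libraries.

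Shares of UMIs in the NK-like sums were compared without a test. Ribosomal protein genes took 20.4 ± 2.19% in blood and 24.5 ± 5.11% in tumor (SD, n = 5), with 21.7% in both tissues of donor 1. Mitochondrial genes took 3.17 ± 0.850% in blood and 2.49 ± 0.665% in tumor, lower in tumor in 5 of 5 donors. Heat shock genes took 0.216 ± 0.0321% in blood and 0.494 ± 0.286% in tumor. The 35 melanoma-like cells of blood held 1 count of PMEL among 375454 UMIs, so their name is uncertain.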
